A study of Escherichia coli with 6 samples.

How the data were processed

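The samples were stationary-phase cultures of Escherichia coli K-12 grown in Lysogeny broth at 37 °C and 200 rpm and collected at 16 h, per the labels' protocols. The labels name 6 samples in 3 groups, with 2 biological replicates per strain. ZK126 carries wild-type rpoS in a W3110 background with a lac deletion, ZK819 carries the rpoS819 allele and streptomycin resistance, and ZK92 is ZK819 with the rpoS92 allele and a Tn10 insertion in tna. Total RNA was treated with DNase, ribosomal RNA was depleted, and libraries were made with the TruSeq RNA v2 kit, which does not mark strand. Reads from a gene and from an antisense or overlapping partner could therefore not be told apart.

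FastQC, BWA and DESeq were used, per the submitters' processing notes, which give no versions. The genome build and the read counter are not given in the sources used here. Each of the 2 deposited tables lists 4151 genes and sets a mutant against wild-type rpoS, per the file headers. The authors deposited group means of normalized read counts, a signal made by dividing the counts by DESeq size factors. The deposited fold change is the ratio of the mutant mean to the wild-type mean, and the deposited log2 fold change is the log2 of that ratio with no pseudocount. The deposited p-value and adjusted p come from DESeq, per the submitters' processing notes, and 4024 genes have one in each table.

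The deposited overall mean weighs the wild-type mean and the rpoS819 mean 2 to 1 in each of the 4151 genes, so that 1 rpoS819 library entered the authors' comparison although the labels name 2. The rpoS92 table weighs both means equally. Every group mean was a whole-number combination of 1 step per library, and whole reads were recovered for each gene in all 5 libraries within a tolerance of 1e-06 reads. The wild-type reads from both tables were identical for 4151 genes. The libraries are called wild-type A and B, rpoS819, and rpoS92 A and B, with A the deeper of a pair, and carry no replicate number. The recovery was tested on simulated data, where both counts were recovered for 4151 of 4151 genes.

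Wild-type A held 5623735 reads, wild-type B 4526248, rpoS819 581745, rpoS92 A 732492 and rpoS92 B 636821. The median gene had 170 reads in wild-type A, 142 in wild-type B, 18 in rpoS819, 23 in rpoS92 A and 14 in rpoS92 B. On a common scale over the 5 libraries, 3 reads equalled a normalized count of 0.733 in wild-type A, 0.876 in wild-type B, 7.40 in rpoS819, 5.54 in rpoS92 A and 8.89 in rpoS92 B. Folds against a library without a read were computed against this floor of 3 reads per library, on the scale of the table they come from. Reads carried no molecular identifiers, so floors and intervals cover counting error only. Folds from 1 to 3 reads are given with an exact Poisson interval at 95%.

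The design fixed before the data were examined expected counts, normalized values or the authors' comparison, and named a test for each. Because the tables hold the authors' comparison, each mutant was set against wild type by the authors' deposited adjusted p at a threshold of 0.05. The remaining pair, rpoS92 against rpoS819, was tested with limma-trend on log2 of the recovered normalized value plus 1, for genes with a mean of at least 10, with the 5 libraries in 1 fit and 2 residual degrees of freedom. The recovered reads were also tested with edgeR's quasi-likelihood test (TMM scaling, default expression filter) and with DESeq2, and edgeR counts of calls stand beside the deposited ones for each list with a deposited call. Standard errors given for edgeR were approximated from the log2 fold change and the F statistic. Adjusted p-values are Benjamini-Hochberg values.

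Before the data were examined, 23 gene lists were fixed from textbook knowledge. For each list the text gives the members past the threshold, over all genes and adjusted over the list alone. Lists were tested with camera on the limma-trend fit at a preset correlation of 0.01 and with an estimated correlation, and with fry. The p at the preset correlation takes genes as its units and does not measure the spread between cultures. Estimated correlations exceeded 0.01 in some lists, such as general stress (0.131) and ribosomal proteins (0.755), and were negative in others. With an estimated correlation, camera uses the 2 residual degrees of freedom, so hardly any list could pass. It therefore cannot show whether correlation between genes explains a call. Median log2 fold changes of lists come from the limma-trend fit. Named genes were rpoS and the genes of the strain genotypes, up to 10 genes per direction with the largest change past the threshold and a mean of at least 50, and up to 3 members per list by the same minimum. For the pair of mutants, they were the 10 largest differences per direction among genes past the threshold in at least 1 comparison. Further genes are named where few members of a list moved or where a gene stood out, and these were chosen after their values were seen. They include asr, ydcT, ydcU, proV, proW, proX, csgG, fliR, ymgA, ymgB, gadW, cspE, clpB, rmf and zntA, and the members of lists named for the pair of mutants.

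The overlap of the comparisons was set against the overlap of independent lists and against 50 simulated unchanged pairs of groups sharing the wild-type libraries. A reference gene table of strain MG1655 (assembly ASM584v2) was used only for names and for which genes neighbour each other. Of the 4151 gene names, 4117 matched, 3497 by symbol and 620 by synonym, and 34 did not. Genes are named as in the deposited tables.

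The gene tests were tested on simulated counts with 200 genes changed 4-fold or 8-fold. For rpoS819 against wild type, edgeR recovered 94% of the 4-fold and 100% of the 8-fold changes, with 17 false calls among 2885 genes tested. For rpoS92 against wild type, it recovered 100% at both sizes, with 8 false calls among 2993 genes. For rpoS92 against rpoS819, limma-trend recovered 97% of the 4-fold and 100% of the 8-fold changes with 57 false calls among 3068 genes, and edgeR recovered 91% and 100% with 19 false calls among 2975 genes. The edgeR call is therefore given beside the limma-trend call for that pair. The simulated groups shared 1 spread per gene. In the data, the chi-square per degree of freedom between the libraries of a pair was 4.87 in wild type and 36.1 in rpoS92. The simulation therefore does not show how the tests perform when the spread differs between groups.

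Alternatives covered the test, size factors, filters, thresholds, pseudocounts, each library left out in turn, wild-type reads thinned to the depth of the mutants, the 10 most abundant genes left out, and the background, membership and operon structure of the lists. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.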

Results

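The transcriptomes of 3 Escherichia coli strains that differ in rpoS, the gene of the stationary-phase sigma factor sigma S, were compared after 16 h of growth. By their labels the mutant strains also carry streptomycin resistance, and the rpoS92 strain a Tn10 insertion in tna. The labels name 2 cultures per strain, and the deposited tables hold 2 wild-type libraries, 1 rpoS819 library and 2 rpoS92 libraries. The wild-type libraries held 5623735 and 4526248 reads, the rpoS819 library 581745, and the rpoS92 libraries 732492 and 636821. The wild-type libraries correlated at r = 0.996 across 3100 genes and the rpoS92 libraries at r = 0.913, where genes are not independent replicates. The deepest mutant library was 6.18-fold shallower than the shallowest wild-type library, so that depth and genotype coincide. The rpoS819 values have no replicate, so that every difference involving that strain rests on 1 library.

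The rpoS message itself was present in every library, and its level was higher in the rpoS819 library. Its normalized count was 3178 ± 260 in wild type (SD, n = 2), 8345 in rpoS819 and 5459 ± 1716 in rpoS92 (SD, n = 2). In the authors' deposited table for rpoS819, rpoS rose by 1.34 on the log2 scale (DESeq adjusted p = 5.9e-16). The edgeR change was 1.39 (SE 0.35, adjusted p = 0.0384) and not past the threshold without wild-type A (1.48) or without wild-type B (1.35), and limma-trend did not call it (1.39, SE 0.37, adjusted p = 0.055). For rpoS92 the authors' deposited table lists a log2 fold change of 0.78 (DESeq adjusted p = 0.823). The message level does not show which allele a library carries. Of the lac genes, lacY and lacA had no read in any library and lacI had 1 read, in wild-type A. The lacZ gene had 0 reads in wild type, 16 in rpoS819 and 1 in rpoS92 B, and passed the threshold in the authors' deposited table for rpoS819 (DESeq adjusted p = 9.6e-20), so that the lac deletion of the labels was not matched by lacZ in that library. In rpoS819, the authors' deposited table has tnaA, the tryptophanase gene, up by 1.15 and rpsL, the ribosomal protein gene in which streptomycin resistance commonly arises, at -2.14, both past the threshold, although edgeR did not call tnaA (1.20, SE 0.43, adjusted p = 0.0916). For rpoS92 the authors' deposited table gives tnaA 0.09 and rpsL -1.13, neither past the threshold. The tnaA value has no settled sign, with -0.053 by edgeR, -0.078 by limma-trend and -0.83 by edgeR without rpoS92 B, and its normalized counts were 27.7 and 74.1 in the rpoS92 libraries.

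**Figure D1:**
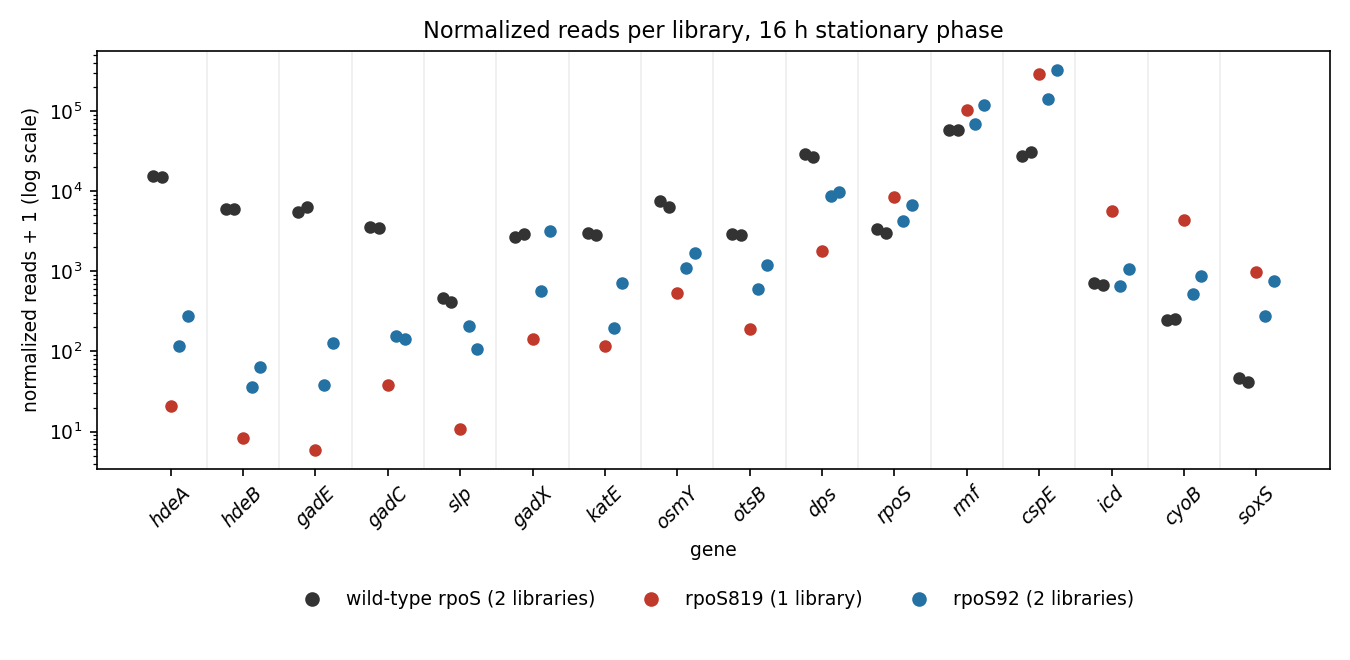
Normalized read count plus 1 (log axis) of 16 genes in each of the 5 libraries, with 1 point per library coloured by strain. The hdeA count was 15235 on average in wild type, 19.7 in rpoS819 and 196 on average in rpoS92.

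The first comparison asked how the stationary-phase transcriptome of the rpoS819 strain differed from that of wild type. In the authors' deposited table, 15 of 22 acid resistance genes and 63 of 75 general stress genes fell, while 13 of 20 TCA cycle genes rose. Over all 4024 genes with a p, the same test called 45.2%, with 867 higher and 951 lower. List counts in this comparison are to be read against those shares. The normalized count of hdeA, a periplasmic acid chaperone gene, was 15235 ± 294 in wild type (SD, n = 2) and 19.7 in rpoS819. By edgeR the hdeA log2 fold change was -9.59 (SE 0.88, adjusted p = 0.00578). The catalase gene katE, a classical sigma S target, changed by -4.65 by edgeR (SE 0.91, adjusted p = 0.0194), and cyoC, a subunit of cytochrome bo oxidase, changed by 4.35 (SE 0.29, adjusted p = 0.00481).

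Of 75 measured general stress genes, 63 fell, 5 rose and 7 were not past the threshold in the authors' deposited table for rpoS819, and 65 fell and 5 rose when adjusted over the list alone. The edgeR test called 46 lower and 3 higher. The largest falls by the authors' deposited table were yciF (-5.75 from 3 reads in rpoS819, exact Poisson 95% interval -8.03 to -4.21), katE (-4.71) and yciE (-4.66). Median log2 fold change of the list was -1.92 (camera adjusted p = 1.11e-11, and adjusted p = 0.559 with an estimated correlation). The risers included ydcU (1.64) and ydcT (1.35) in the authors' deposited table, named after their values were seen and known as parts of a putative ABC transporter.

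Of 22 acid resistance genes, 15 fell, 1 rose and 6 were not past the threshold in the authors' deposited table, with 16 and 1 when adjusted over the list alone. The edgeR test also called 15 lower and 1 higher. For gadE, the central activator of acid resistance, the authors' deposited table lists -10.28 from 2 reads in rpoS819 (exact Poisson 95% interval -13.32 to -8.43). It lists -9.73 for hdeB from 3 reads (-12.01 to -8.18) and -9.67 for hdeD from 1 read (-14.97 to -7.19) in the authors' deposited table. The glutaminase gene ybaS and yhiD had no read in rpoS819, which makes them at least 80.03-fold and at least 60.02-fold lower than in wild type against the floor of 3 reads. For gadA and gadB the authors' deposited table lists -8.18 and -8.36 from 2 reads each (-11.22 to -6.32 and -11.41 to -6.51), uncertain individually because these glutamate decarboxylase genes are nearly identical, while the antiporter gene gadC stood at -6.62. The list's median was -5.06, also with ybaS and yhiD at their bounds (camera adjusted p = 3.50e-07, and adjusted p = 0.472 with an estimated correlation). The riser, named after its value was seen, was asr, an acid shock gene, at 3.63 in the authors' deposited table.

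Related stationary-phase lists held members past the threshold, and camera called none of the 3 described here. Among 21 trehalose and osmotic protection genes, 10 fell and 4 rose in the authors' deposited table and when adjusted over the list alone, and edgeR called 8 lower and 2 higher. The trehalose synthesis genes otsA (-3.94) and otsB (-3.97) and the periplasmic gene osmY (-3.74) led the falls in the authors' deposited table. The risers were treA and the glycine betaine uptake genes proV (2.09), proW (3.10) and proX (1.47) of the authors' deposited table, named after their values were seen, and camera did not call the list (adjusted p = 0.135). Of 20 curli and cyclic di-GMP genes, 10 fell and 1 rose in the authors' deposited table and adjusted over the list alone, led by the regulator mlrA (-2.23), and the riser was csgG (1.39). For curli and cyclic di-GMP, edgeR called 3 lower and 1 higher, and camera gave adjusted p = 0.0589. Of 19 arginine, GABA and glutarate catabolism genes, 12 fell and 2 rose by the deposited test and adjusted over the list alone. By edgeR 1 was lower and 0 higher. Camera did not call this list (adjusted p = 0.179), and fry called it lower (adjusted p = 0.0174).

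The TCA cycle and aerobic respiration lists had more rises than falls in rpoS819. Of 20 TCA cycle and glyoxylate shunt genes, 13 rose and 2 fell in the authors' deposited table and adjusted over the list alone, and edgeR called 12 higher and 1 lower. The authors' deposited table lists 3.28 for fumA, 3.10 for sucB and 2.96 for icd, which encode enzymes of the cycle. The list's median was 2.21 (camera adjusted p = 9.16e-05, and adjusted p = 0.472 with an estimated correlation). Of 31 aerobic respiration and ATP synthase genes, 15 rose and 2 fell in the deposited test and adjusted over the list alone, and edgeR called 5 higher and 1 lower. The cytochrome bo oxidase genes cyoC (4.30), cyoB (4.07) and cyoD (3.75) led in the authors' deposited table, and the list's median was 0.51 (camera adjusted p = 0.0265, and adjusted p = 0.559 with an estimated correlation). Anaerobic respiration and hydrogenases had 0 rises and 6 falls among 45 genes, 5 adjusted over the list alone and 3 by edgeR (camera adjusted p = 0.13), with the fumarate reductase gene frdB at -1.53 in the authors' deposited table.

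Nutrient uptake groups rose in part. Of 74 carbohydrate genes under the regulator CRP, 28 rose and 11 fell in the deposited test and adjusted over the list alone, and edgeR called 19 higher and 6 lower (median 0.53, camera adjusted p = 0.0416, and adjusted p = 0.559 with an estimated correlation). The ribose uptake genes rbsA (3.79) and rbsD (3.52) and the trehalose transporter gene treB (3.10) led in the authors' deposited table. Iron uptake genes had 12 rises and 0 falls among 36 in the deposited test and adjusted over the list alone, and 8 and 0 by edgeR (median 0.37, camera adjusted p = 0.0129, and adjusted p = 0.559 with an estimated correlation). Examples from the authors' deposited table were the enterobactin uptake gene fepD (2.23) and tonB (1.61). Amino acid and peptide uptake and catabolism had 26 rises and 9 falls among 58 genes, also adjusted over the list alone, and 12 and 5 by edgeR (camera adjusted p = 0.0977), with putA at 2.74, aspA at 2.51 and sdaA at -2.23 in the authors' deposited table. Amino acid biosynthesis had 15 rises and 13 falls among 68 genes, 14 and 13 adjusted over the list alone, and 4 and 7 by edgeR (camera adjusted p = 0.888). The deposited counts of that list lie near the shares over all genes.

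Translation factor genes fell more often than they rose, and ribosomal protein genes were called in both directions. Of 22 translation factor and RNA polymerase genes, 13 fell and 1 rose in the deposited test, 14 and 1 adjusted over the list alone, and edgeR called 6 lower and 0 higher (median -0.48, camera adjusted p = 0.0129, and adjusted p = 0.559 with an estimated correlation). The elongation factor genes fusA (-2.40) and tsf (-2.24) led in the authors' deposited table. Of 54 ribosomal protein genes, 10 were called up and 13 down in the deposited test, also adjusted over the list alone, but edgeR called 0 up and 4 down, with a median of 0.02 and a mean of -0.03 (camera adjusted p = 0.888). Those deposited counts lie near the shares of calls over all genes. Of 11 ribosome hibernation genes, 3 rose and 6 fell, 3 and 7 adjusted over the list alone, and 1 and 4 by edgeR (camera adjusted p = 0.247). In the authors' deposited table, elaB stood at -3.53, yqjD at -2.54 and yfiA, a hibernation factor gene, at 2.28.

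Stress and envelope lists held members called in both directions by the deposited test, and camera called none of them. Calls in both directions were also the pattern over all genes. Oxidative stress defence had 7 rises and 12 falls among 25 genes, also adjusted over the list alone, and 4 and 6 by edgeR (camera adjusted p = 0.637). In the authors' deposited table soxS, an activator of the superoxide response, stood at 4.43 and dps, which encodes a DNA-binding protein of stationary phase, at -4.01. Heat shock chaperones and proteases had 5 rises and 10 falls among 20, also adjusted over the list alone, but 4 rises and 2 falls by edgeR, with a median of -0.25 and a mean of 0.22 (camera adjusted p = 0.977), and the membrane protease gene htpX stood at 3.40 in the authors' deposited table. Phosphate starvation genes had 2 rises and 8 falls among 23, also adjusted over the list alone, and 1 and 4 by edgeR (camera adjusted p = 0.247). Fry did call this list lower (adjusted p = 0.0114). In the authors' deposited table phoE stood at 3.24 and pstS at -1.97. Outer membrane porins and envelope stress had 10 rises and 13 falls among 27, 10 and 14 adjusted over the list alone, but 7 rises and 5 falls by edgeR, with a median of -0.42 and a mean of 0.16 (camera adjusted p = 0.977), and the authors' deposited table has ompF, a major porin gene, at 3.65. Sigma factors and regulators of sigma S had 10 rises and 8 falls among 27, 10 and 9 adjusted over the list alone, and 6 and 3 by edgeR, with a median of -0.02, a mean of 0.18 and an upward camera direction (adjusted p = 0.637). That list includes crl, whose product helps sigma S bind RNA polymerase, at 2.39 and rssB, whose product delivers sigma S to proteolysis, at -1.79 in the authors' deposited table. The SOS list had 8 rises and 7 falls among 22, also adjusted over the list alone, and 6 and 2 by edgeR (camera adjusted p = 0.527). Flagella and chemotaxis had 1 and 2 among 53, with 1 and 1 adjusted over the list alone and 0 and 2 by edgeR (camera adjusted p = 0.637). The genotype genes had 3 and 1 among 6, lacZ among the rises against a wild-type mean of 0, also adjusted over the list alone, and 2 and 1 by edgeR (camera adjusted p = 0.905).

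In total, 1818 of 4024 genes with a p passed the authors' deposited test for rpoS819, 867 higher and 951 lower, and edgeR called 931, of which 930 were also called in the deposited table in the same direction. Beside the list members, the largest rises in the authors' deposited table included hokB (4.32), a toxin gene, ucpA (4.30), yqeC (4.37), uidB (4.02) and dsbB (3.89). Also among them were insJ (4.55) and insK (4.12), genes of an insertion element whose copy number in these strains was not tested. Only the wild-type pair has replicates in that table. In the fit of 5 libraries, edgeR called 4 genes without wild-type A, 4 without wild-type B, 1966 without rpoS92 A and 1964 without rpoS92 B.

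**Figure D2:**
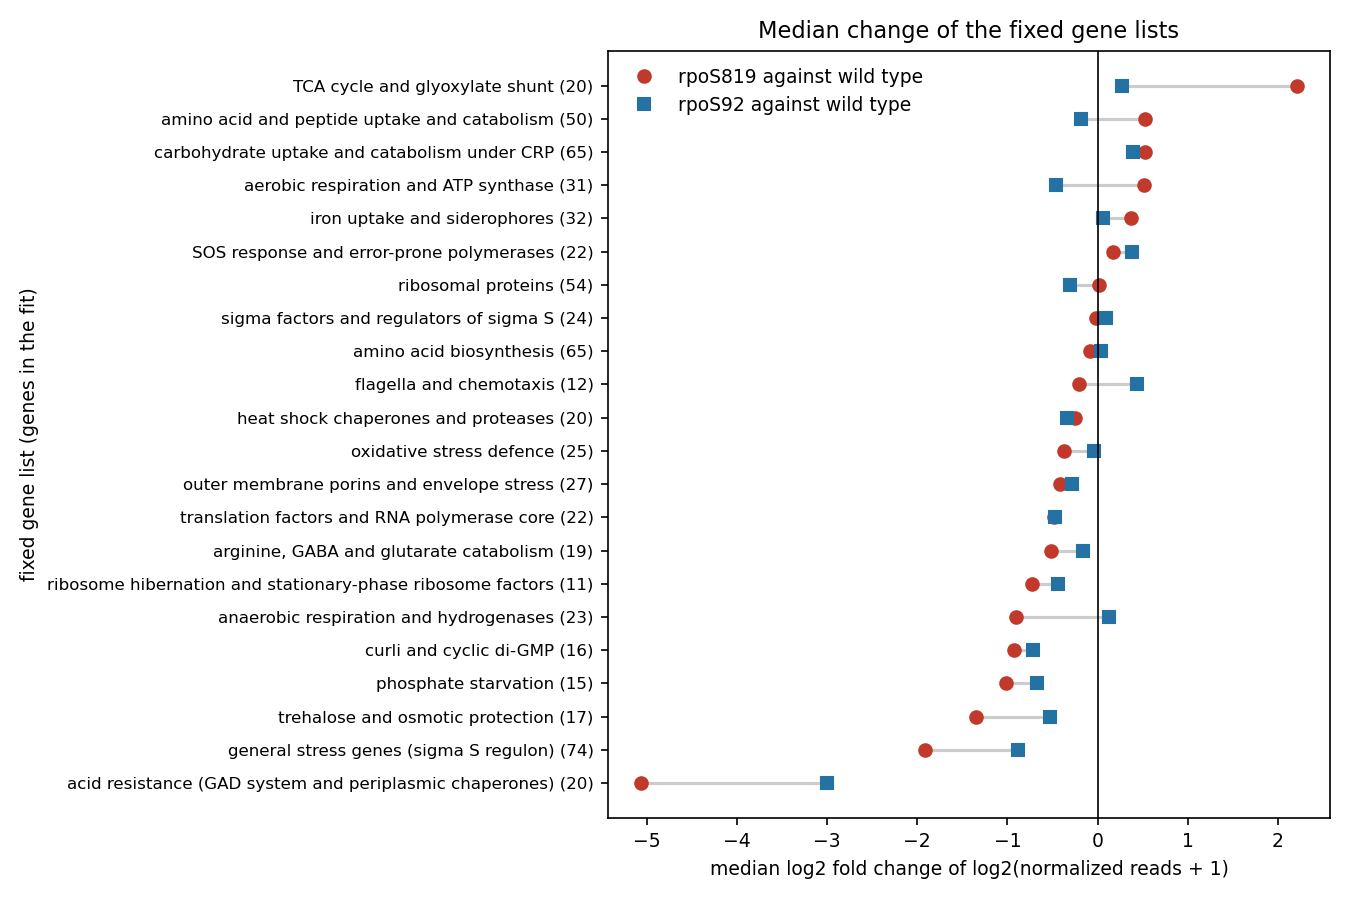
Median log2 fold change against wild-type rpoS of the fixed gene lists in rpoS819 (circles) and rpoS92 (squares), from the limma-trend fit, without the genotype list. The acid resistance list lies at -5.06 in rpoS819 and -3.00 in rpoS92, and the TCA cycle list at 2.21 and 0.27.

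The second comparison asked the same of the rpoS92 strain, which carries that allele in the rpoS819 background. In the authors' deposited table for rpoS92, 12 of 22 acid resistance genes and 20 of 75 general stress genes fell. The normalized count of hdeA was 196 ± 113 in rpoS92 against 15235 ± 294 in wild type (SD, n = 2 each). By edgeR the hdeA log2 fold change was -6.32 (SE 0.53, adjusted p = 0.0128), with both rpoS92 libraries below both wild-type libraries. The edgeR log2 fold change of katE was -2.73 (SE 0.60, adjusted p = 0.0382).

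Of 22 acid resistance genes, 12 fell, 0 rose and 10 were not past the threshold in the authors' deposited table for rpoS92, with 13 lower and 1 higher adjusted over the list alone and by edgeR. The authors' deposited table lists -7.27 for yhiD from 3 reads in rpoS92 (exact Poisson 95% interval -9.55 to -5.73), -6.95 for hdeB, -6.16 for gadE and -4.56 for gadC. The list's median was -3.00 (camera adjusted p = 5.69e-06, and adjusted p = 0.656 with an estimated correlation). Of 75 general stress genes, 20 fell, 2 rose and 53 were not past the threshold, with 27 and 3 adjusted over the list alone and 29 and 4 by edgeR. Among the falls, yciE stood at -3.42, yciF at -3.15 and katE at -2.68 in the authors' deposited table. The risers were again ydcU (1.85) and ydcT (1.68) in the authors' deposited table. The median of this list was -0.88 (camera adjusted p = 3.83e-06, and adjusted p = 0.656 with an estimated correlation). Fry did not call the list (adjusted p = 0.0772).

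Further lists had few members past the deposited test for rpoS92, which called 3.08% of all genes, and edgeR called more in most of them. Trehalose and osmotic protection had 3 falls among 21 genes, 4 adjusted over the list alone, and 5 falls and 1 rise by edgeR. The deposited falls were osmY (-2.29), otsA (-2.25) and otsB (-1.68) in the authors' deposited table. The curli list had 1 fall, gmr at -1.64 in the authors' deposited table, and 2 falls adjusted over the list alone, against 4 falls and 1 rise by edgeR. Ribosome hibernation had 2 falls, yqjD (-1.96) and elaB (-1.85) in the authors' deposited table, and 2 falls and 1 rise adjusted over the list alone, against 3 and 1 by edgeR. The chaperonin genes groS (-2.30) and groL (-2.05) of the authors' deposited table were the falls of the heat shock list, which had 2 falls and 1 rise adjusted over the list alone and 3 falls and 2 rises by edgeR. Amino acid uptake had 2 rises and 0 falls, 2 and 1 adjusted over the list alone and 5 and 5 by edgeR, with putA (2.10) and aspA (1.94) in the authors' deposited table, and a median of -0.19, a mean of 0.04 and an upward camera direction (adjusted p = 0.845). The histidine synthesis genes hisD (2.26) and hisG (2.24) of the authors' deposited table rose in the amino acid biosynthesis list, which had 2 rises and 1 fall adjusted over the list alone and 7 and 5 by edgeR. Iron uptake had 2 rises, fepD (2.27) and the sigma factor gene fecI (2.16) in the authors' deposited table, also adjusted over the list alone, and 3 by edgeR. The riser of the sigma factor list was fecI too, where edgeR called 3 rises and 1 fall. Carbohydrate genes had 1 rise, rbsA (2.76), and 1 fall, nanK (-1.68), in the authors' deposited table and adjusted over the list alone, but 13 rises and 3 falls by edgeR. In the oxidative stress list katE was the fall of the deposited test, also adjusted over the list alone, and edgeR called 6 falls and 2 rises.

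No member of the translation factor list passed the authors' deposited test for rpoS92, although camera called the list lower (median -0.48, adjusted p = 0.0296, and adjusted p = 0.656 with an estimated correlation), and edgeR called 1 lower. In the porin list 0 genes passed, with 1 rise and 1 fall adjusted over the list alone, and 2 rises and 4 falls by edgeR. The lists for arginine and GABA catabolism, flagella, ribosomal proteins, TCA cycle, aerobic respiration, anaerobic respiration, phosphate starvation, SOS and genotype genes had 0 calls by the authors' deposited test, also adjusted over the list alone. By edgeR, the TCA cycle list had 3 rises and 1 fall and the aerobic respiration list 5 rises and 4 falls in rpoS92. The other lists of these had at most 2 rises and 3 falls by edgeR.

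In total, 124 of 4024 genes passed the authors' deposited test for rpoS92, 35 higher and 89 lower, and 498 had an unadjusted DESeq p under the threshold. The edgeR test called 638 genes, among them 117 of the 124 in the same direction. Among genes past the threshold with a mean of at least 50, the largest rise in the authors' deposited table was ynfM, a putative transporter gene, at a 31.9-fold change. Next on the log2 scale were fimD (3.45), the usher gene of type 1 fimbriae, yhdV (3.27), hokB (2.99) and lpxC (2.92), which encodes an enzyme of lipid A synthesis. The multidrug efflux gene mdtE (-4.07) and yhiM (-3.76) were among the largest falls in the authors' deposited table. The edgeR count was 6 without wild-type A, 5 without wild-type B, 1404 without rpoS92 A and 1781 without rpoS92 B.

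**Figure D3:**
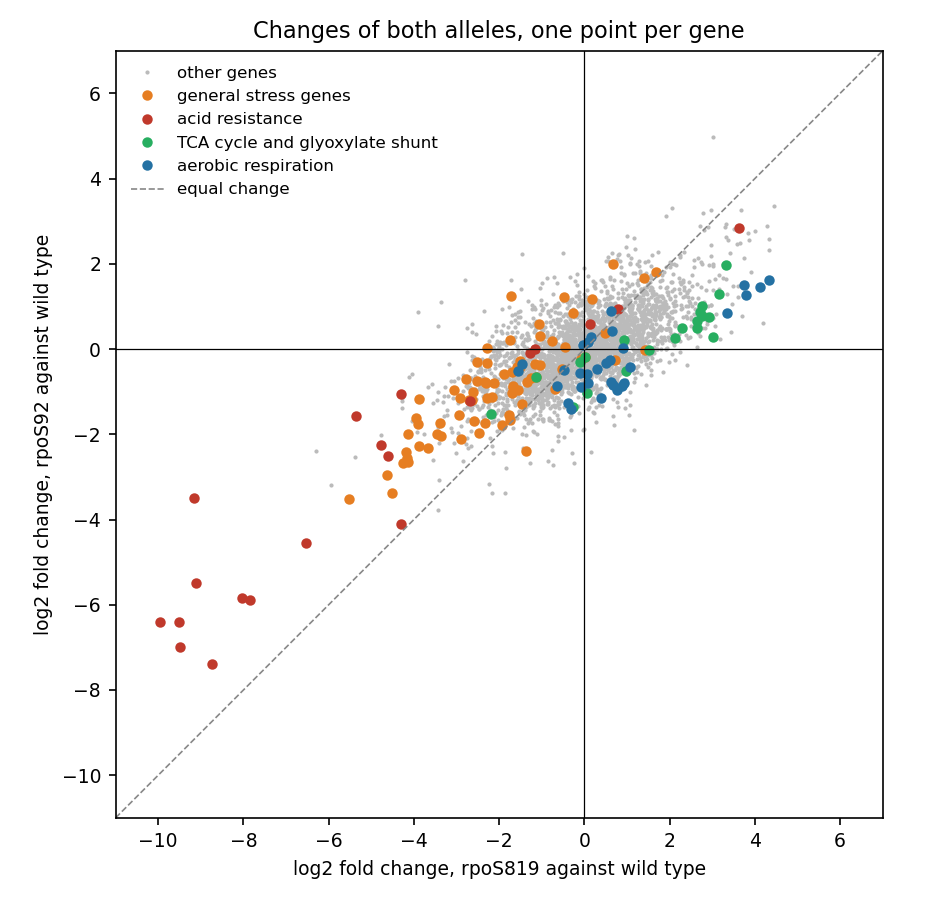
Log2 fold change against wild-type rpoS of each gene in rpoS92 (vertical axis) and rpoS819 (horizontal axis), from the limma-trend fit, with members of selected gene lists marked. Across 3165 genes r was 0.697, against 0.216 for simulated unchanged groups that share the wild-type libraries.

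The third comparison asked whether the mutants differed from each other. By limma-trend, 13 of 75 general stress genes and 8 of 22 acid resistance genes were higher in rpoS92 than in rpoS819, and 10 of 20 TCA cycle genes were lower. For slp, an outer membrane lipoprotein gene of the acid resistance region, the limma-trend difference was 3.78 (SE 0.45, adjusted p = 0.0399, edgeR adjusted p = 0.0438). The slp value of rpoS819 was 17.0 in the authors' deposited table, where 1 read equals 4.25, so the difference rests on few reads. The limma-trend SE does not allow for the lower depth of that library. The difference for dps was 2.35 (SE 0.28, limma adjusted p = 0.0399, edgeR adjusted p = 0.0418). For icd, the isocitrate dehydrogenase gene, it was -2.74 (SE 0.36, limma adjusted p = 0.0399, edgeR adjusted p = 0.0417).

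Of 75 general stress genes, 13 were higher and 0 lower in rpoS92 by limma-trend, 28 and 0 adjusted over the list alone, and 13 and 0 by edgeR. The list's median difference was 1.20 (camera adjusted p = 1.20e-09, and adjusted p = 0.618 with an estimated correlation). Fry did not call the list (adjusted p = 0.0582). The genes wrbA (2.31), talA (2.11) and yhbO (2.08) were among the members called by both tools, named after their values were seen. Acid resistance had 8 higher and 0 lower, 9 and 0 adjusted over the list alone, and 5 and 0 by edgeR (median 2.04, camera adjusted p = 4.15e-06, and adjusted p = 0.252 with an estimated correlation). The limma difference of hdeA was 3.12 (SE 0.55, adjusted p = 0.0482), and edgeR did not call it (adjusted p = 0.0642). For the regulator gene gadX the difference was 3.25 (SE 1.06, limma adjusted p = 0.126, edgeR adjusted p = 0.117), not past the threshold.

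Of 20 TCA cycle genes, 10 were lower and 0 higher in rpoS92 by limma-trend and by edgeR, 13 and 0 adjusted over the list alone (median -1.65, camera adjusted p = 1.75e-06, and adjusted p = 0.252 with an estimated correlation). Aerobic respiration had 8 lower and 0 higher by both tools, 10 and 1 adjusted over the list alone (median -0.86, camera adjusted p = 1.40e-05, and adjusted p = 0.252 with an estimated correlation), including cyoC (-2.73), cyoB (-2.68) and cyoD (-2.52), each called by both tools. Anaerobic respiration had 1 higher, also adjusted over the list alone (median 0.93, camera adjusted p = 0.00318, and adjusted p = 0.759 with an estimated correlation), and edgeR called 0. Amino acid uptake had 3 lower, also adjusted over the list alone, and 2 by edgeR (median -0.52, camera adjusted p = 0.0309, and adjusted p = 0.618 with an estimated correlation). Iron uptake had 1 higher, fecI (1.59), and 1 lower, fhuE (-1.71), also adjusted over the list alone, where edgeR called both of these and had 1 higher and 2 lower (median -0.56, camera adjusted p = 0.0309, and adjusted p = 0.759 with an estimated correlation). Camera called none of the other 16 lists, in each of which limma-trend and edgeR called at most 2 genes higher and 2 lower. In the SOS list the median (-0.16) and the mean (0.12) differed in sign.

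Over all genes, limma-trend called 240 of 3165, 154 higher and 86 lower in rpoS92, and edgeR called 195, 96 higher and 99 lower, with 174 genes called by both. Among the largest differences, ycdG (4.42), ymgC (3.90), yajB (3.71), yhiO (2.96), gcd (2.90) and ydbK (2.90) were higher and yqeC (-3.56) and htpX (-3.05) lower by limma-trend, each also past edgeR's threshold. The ycdG value rests on 2 reads in rpoS819, where the authors' deposited table lists -3.09 against wild type (exact Poisson 95% interval -6.14 to -1.24). The ymgC and yajB values also rest on few reads in rpoS819, at 17.0 and 34.0 in the authors' deposited table, where 1 read equals 4.25. The porin gene ompF (-2.92, limma adjusted p = 0.0813, edgeR adjusted p = 0.0622) did not pass, and spr (-2.95) passed by edgeR (adjusted p = 0.0417) and not by limma-trend (adjusted p = 0.0579). Limma-trend called 0 genes without wild-type A or without wild-type B (441 and 434 at an unadjusted p under the threshold, with 0 by edgeR in both cases), 2293 without rpoS92 A and 2392 without rpoS92 B. In simulated data the limma-trend calls for this pair included more false ones than edgeR's, and a larger share of false ones than the threshold of 0.05.

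The comparisons against wild type overlapped. Of 4021 genes tested in both deposited comparisons, 32 rose in both and 86 fell in both, where independent lists would share 7.55 and 21.0. Simulated unchanged groups sharing the wild-type libraries gave 0 shared calls by limma-trend, where 102 rises and 131 falls were shared. Those groups hold no changed genes, so this 0 does not measure how much overlap shared controls add to real changes. The covariance of the limma-trend fold changes was 0.966, against 0.0378 in the simulated groups, and 72.2% of genes had the same sign against 58.0%. With rpoS819 set against 1 wild-type library and rpoS92 against the other, r was 0.684 and 0.690. These pairings share no wild-type library, but each fold change in them rests on 1. Part of the excess of the deposited overlap over that of independent lists may come from the shared controls. A library batch that follows the depth would also be shared by both comparisons. Neither the simulated groups nor these pairings can address it. Opposite calls numbered 4 by edgeR and 5 by limma-trend. In the deposited comparisons there was 1, zntA, a zinc exporter gene, at -0.56 in the authors' deposited table for rpoS819 and 2.27 in the authors' deposited table for rpoS92.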

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

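The limma-trend and camera tests of the difference between the mutants were planned before the data were examined, and the tests of technical explanations were chosen after the results they address were seen. The differences listed first stand out because the gene or the median of the list lay on opposite sides of wild type in the mutants and the difference between them passed its test, for the lists at the preset correlation. The zinc exporter gene zntA was 2.74 higher on the log2 scale in rpoS92 than in rpoS819 by limma-trend (SE 0.30, adjusted p = 0.0399, edgeR adjusted p = 0.0417), with normalized counts of 410 and 414 in wild type, 291 in rpoS819, and 1632 and 2339 in rpoS92. It is listed as the only gene called in opposite directions in the deposited comparisons, since 94 of the 240 genes called between the mutants by limma-trend lay on opposite sides of wild type. Of those 94, the others named for this comparison were ycdG (4.42, from 2 reads in rpoS819), yajB (3.71), yhiO (2.96) and ydbK (2.90), chosen after their values were seen and each also past edgeR's threshold. The aerobic respiration list had a median difference of -0.86 (camera adjusted p = 1.40e-05, and adjusted p = 0.252 with an estimated correlation), with medians of 0.51 in rpoS819 and -0.46 in rpoS92, where camera did not call it against wild type (adjusted p = 0.331). For amino acid and peptide uptake the median difference was -0.52 (camera adjusted p = 0.0309, and adjusted p = 0.618 with an estimated correlation), with medians of 0.53 and -0.19, although camera called it against wild type in neither rpoS819 (adjusted p = 0.0977) nor rpoS92 (adjusted p = 0.845), where its mean was 0.04 and its camera direction upward. For anaerobic respiration it was 0.93 (camera adjusted p = 0.00318, and adjusted p = 0.759 with an estimated correlation), with medians of -0.90 and 0.13, neither called against wild type (camera adjusted p = 0.13 and 0.364).

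The deposited rpoS819 comparison called 1818 genes and the deposited rpoS92 comparison 124. A fit that takes its spread from the wild-type pair alone could account for part of this gap, since edgeR with the wild-type pair and 1 rpoS92 library called 1773 genes with rpoS92 A and 1378 with rpoS92 B. The rpoS819 profile also lay farther from wild type, with a median absolute log2 fold change of 0.89 over 2018 genes, against 0.69 and 0.58 in the rpoS92 libraries and 0.09 between the wild-type libraries. Both explanations stay open, and the counts of calls therefore may not rank the alleles. When edgeR was given the wild-type pair and 1 mutant library at a time, rpoS819 still had more calls than either rpoS92 library. The gap was then far smaller than in the deposited comparisons. Such fits rest on 1 library per mutant and on another test than the deposited one, so the share of each explanation was not measured.

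Many acid resistance genes had few reads in the mutants. The run of 12 neighbouring genes from slp to gadA held 99 reads in rpoS819, 639 in rpoS92 A and 1382 in rpoS92 B, against 142807 and 120261 in wild type. Not every gene of the run fell this far. The gadX gene gave 303 reads in rpoS92 A and 1086 in rpoS92 B. It stood at -0.56 in the authors' deposited table for rpoS92 and was not past the threshold (DESeq adjusted p = 0.902). Loss of the whole run in the mutant strains is argued against by the reads it held, of which 57 in rpoS819 and 1086 in rpoS92 B were gadX reads. The gene gadC outside the run was 94.7-fold lower in rpoS819 and 22.6-fold and 24.7-fold lower in rpoS92. That fall cannot decide, because gadE, the central activator of acid resistance, lies in the run and would be lost with it. Lower depth is argued against as well, since 14184 reads were expected in the run in rpoS819 at the wild-type level. A shorter deletion in rpoS819 was not tested, although rpoS92, which descends from the rpoS819 strain by its label, had reads there. An effect of the rpoS alleles, of the other labelled differences (streptomycin resistance, and the Tn10 insertion in ZK92) and of a library batch that follows the depth stay open, untested.

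The share of reads from cspE, a cold shock family gene chosen after its values were seen, was 1.97% and 2.35% in wild type, 19.8% in rpoS819, and 10.3% and 17.2% in rpoS92. Reads moving between cspE and its paralogs are argued against, since the summed share of the csp family rose at least 3.53-fold over the higher wild-type share in each mutant library. A library batch that follows the depth cannot be told apart from an effect of the alleles, because the shallowest wild-type library was 6.18-fold deeper than the deepest mutant library and no wild-type library of low depth exists. An effect of the rpoS alleles or of the other labelled strain differences stays open, untested.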

How the results depend on the processing

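Alternatives planned before the data were examined were DESeq2, DESeq2 size factors in edgeR, filters on means, thresholds, Benjamini-Yekutieli adjustment, pseudocounts, centring, each library left out, and the list and overlap settings other than the estimated correlation, edgeR and limma-trend counts. The others were chosen after seeing the data. For rpoS819 against wild type, the deposited 1818 calls became 931 with edgeR, 882 with limma-trend, 688 with DESeq2, 910 with DESeq2 size factors in edgeR, 887 without edgeR's filter, 749 with wild-type reads thinned to 650353 and 925 without the 10 most abundant genes. Leaving out each library in edgeR gave 4 (without either wild-type library) to 1966 (without rpoS92 A; 1964 without rpoS92 B). At 0.01 edgeR called 267 and limma-trend 124, and limma-trend with Benjamini-Yekutieli 5. For rpoS92 against wild type, the deposited 124 became 70 at an adjusted p under 0.01, 59 with Benjamini-Yekutieli, 638 with edgeR, 313 with limma-trend, 380 with DESeq2, 614 with DESeq2 size factors in edgeR, 600 without edgeR's filter, 362 with thinned wild-type reads and 633 without the abundant genes. At 0.01 edgeR called 7 and limma-trend 5, and limma-trend with Benjamini-Yekutieli 0, where 1067 genes had an unadjusted p under 0.05. It became 620 with the wild-type and rpoS92 libraries alone, 1773 with the wild-type pair and rpoS92 A, and 1378 with rpoS92 B, and leaving out each library gave 5 to 1781 (6 without wild-type A, 5 without wild-type B, 620 without rpoS819, 1404 without rpoS92 A, 1781 without rpoS92 B). For rpoS92 against rpoS819, the 240 calls of limma-trend became 0 at 0.01, 0 without a filter and 0 with Benjamini-Yekutieli, where 998, 1120 and 998 genes had an unadjusted p under 0.05 and edgeR called 0 at 0.01 and 158 without a filter. Leaving out each library gave 0 (either wild-type library) to 2392, with 2293 without rpoS92 A and 2392 without rpoS92 B, and the comparison has no value without rpoS819. The fits without a rpoS92 library assume that a lone library varies like the wild-type pair. Genes rising in both comparisons (32) were 14 at 0.01, 156 with edgeR and 102 with limma-trend, and genes falling in both (86) were 53, 246 and 131. With 1 gene per run of adjacent genes, camera called 3 lists for rpoS819, 1 for rpoS92 and 3 between the mutants, where the full lists gave 7, 3 and 7. With an estimated correlation the full lists gave 0 in each comparison, and fry called 7, 2 and 4. That 0 does not show that correlation between genes removed the calls, because camera then has 2 degrees of freedom. For acid resistance in rpoS819 the estimated correlation was negative (-0.0469), yet the camera adjusted p rose from 3.50e-07 to 0.472. Unlike camera, fry called arginine and GABA catabolism, amino acid uptake and phosphate starvation in rpoS819, but not translation factors, carbohydrates or iron uptake. In rpoS92 it called phosphate starvation, but not general stress or translation factors. Between the mutants it called arginine and GABA catabolism, but not general stress, anaerobic respiration, amino acid uptake or iron uptake. Leaving out each library gave 2 to 8 lists for rpoS92, with 8 without rpoS92 B. The rpoS change in rpoS819 stood at 1.39 with limma-trend, no longer past the threshold, and ranged from 1.35 to 1.48 without a library, not past it without either wild-type library. In rpoS92 it ranged from 0.38 to 1.03 and passed the threshold at 1.03 without rpoS92 A and at 0.38 without rpoS92 B. In rpoS92, tnaA, at 0.09 and not past the threshold in the authors' deposited table, turned to -0.053 with edgeR, -0.078 with limma-trend, -0.062 without rpoS819 and -0.83 without rpoS92 B, and tnaC to -1.08 without rpoS92 B. The cause of these changes was not tested, except that filters and omitted libraries change the genes tested and the spread by construction. Named genes kept direction and side of the threshold in 75 of 79 cases with edgeR for rpoS819, and in 4 of 79 without wild-type A. Most of those named genes were chosen for large changes past the deposited threshold in the same reads, which favours keeping the call with edgeR. Of all 1787 deposited rpoS819 calls that edgeR tested, it called 930 in the same direction. No paired analysis was possible because the deposited columns carry no replicate numbers. Depth limits genes with few reads in the mutant libraries, where 38.3% of genes in rpoS819, 32.2% in rpoS92 A and 41.7% in rpoS92 B had fewer than 10 reads.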

Other observations

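The most abundant messages differed between wild type and the mutants, and these genes were chosen after their values were seen. The cold shock family gene cspE, whose product is an RNA chaperone, made up 19.8% of reads in rpoS819 (95% Wilson interval 19.7% to 19.9%), and edgeR gave it a log2 fold change of 3.29 (SE 0.70, adjusted p = 0.0253) in rpoS819 and 2.97 (SE 0.64, adjusted p = 0.0371) in rpoS92. In the authors' deposited table for rpoS92, cspE was 8.02-fold higher and not past the threshold (DESeq adjusted p = 0.625). The disaggregase gene clpB made up 2.24% of reads in rpoS819 (95% Wilson interval 2.21% to 2.28%), 4.79% and 4.81% in rpoS92, and 0.681% and 0.490% in wild type. Its edgeR log2 fold change was 2.02 (SE 0.46, adjusted p = 0.0302) in rpoS819 and 3.28 (SE 0.43, adjusted p = 0.0169) in rpoS92. For rpoS92, the authors' deposited table lists clpB at 3.30, not past the threshold (DESeq adjusted p = 0.118). The hibernation factor gene rmf was the most abundant message of both wild-type libraries at 4.17% and 4.31% of reads, and followed cspE in the mutants at 7.05% in rpoS819 (95% Wilson interval 6.98% to 7.12%) and at 5.08% and 6.21% in rpoS92.

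The genes ymgA, ymgB and ymgC, known for roles in biofilm formation and acid resistance and chosen after their values were seen, stood at -6.09 (ymgA), -5.49 (ymgB) and -6.48 (ymgC) in the authors' deposited table for rpoS819, and at -3.18, -2.50 and -2.37 in the authors' deposited table for rpoS92. Between the mutants, the limma-trend difference was 2.77 for ymgA (SE 0.28, adjusted p = 0.0399, edgeR adjusted p = 0.0417) and 2.86 for ymgB (SE 0.32, adjusted p = 0.0399, edgeR adjusted p = 0.0417). Their rpoS819 values in the authors' deposited table were 29.8 and 59.6, where 1 read equals 4.25. The limma-trend SE does not allow for the lower depth of that library.

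In total, 124 of the 4151 listed genes had no read in any of the 5 libraries. Long neighbouring runs of such genes, in the gene order of the reference strain, were 17 genes from yahL to lacY, 26 from mmuM to yagV, 11 from yagX to ykgD, 11 from betT to yahJ, 4 from mhpR to mhpC, 28 from intR to ynaE and 13 from yghQ to hybB. The run that ends at lacY includes lacA and lacY of the lac region that the strain labels give as deleted, and the run from intR to ynaE is the Rac prophage of the reference strain. The runs between mmuM and mhpC lie in 1 stretch of 80 genes. It held 5 and 7 reads in wild type, 19 in rpoS819 (16 of them lacZ), and 2 in each rpoS92 library. Whether the labelled deletion spans that stretch was not tested.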
